A study of Mus musculus with 10 samples.

How the data were processed

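RNA sequencing of 10 libraries of sorted naive T cells from mouse spleen was analysed, 2 libraries in each of 5 groups: wild-type CD4 (WT CD4), wild-type CD8 (WT CD8), and the CD4hi, DP (CD4 and CD8 positive) and CD4lo cells of OB11 homozygous mice. Per the labels, the authors used 10 ng of total RNA and a directional kit with depletion of ribosomal cDNA. The deposited table holds raw read counts per gene symbol, which the authors made with TopHat2 and HTSeq on build mm10 as their processing notes state, without versions; the gene annotation, strand setting and trimming are not stated. The values are whole numbers from 0 with differing library totals, as raw counts are. A spreadsheet had turned 25 symbols into dates, and these were kept as they stand. No other data type of the study was used here.

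The table has 34573 genes. Library totals ran from 5055956 to 7417789 counts, 63059195 in all. Groups were read from the sample titles, every column matched 1 sample, and no library was left out. Counts have no molecular identifiers, so intervals and floors derived from them cover counting error only; a count of 0 allows up to 3 counts. Between the 2 libraries of a group, the mean chi-square per gene was 3.48 (DP), 3.60 (WT CD8), 6.93 (CD4hi), 8.14 (CD4lo) and 15.1 (WT CD4). It was taken over genes with at least 20 counts summed over the 2 libraries, where pure counting error would give about 1. The symbol with the most counts, AC087541.1, held 11.1% to 16.4% of counts and mitochondrially encoded genes held 13.5% to 16.3%.

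The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the groups, which left 12193 genes holding 99.7% of counts. Counts were scaled by TMM, and all 10 libraries were fitted in 1 edgeR quasi-likelihood model by group, with 5 residual degrees of freedom shared by all groups. Each of 8 comparisons was tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. "Higher" and "lower" refer to the first group named. With 2 libraries against 2, an exact permutation test of a single value cannot go below p = 0.333, so none was run. Of the tested symbols 10991 (90.1%) were found in GENCODE M21, 10150 of them as protein-coding genes; positions come from there.

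Gene lists of 27 pathways and states and of 11 cell types were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. The lists, with members tested of members listed, were CD4 lineage (10 of 10), CD8 lineage (15 of 15), lineage transcription factors (19 of 19), cytotoxic effector (16 of 18), regulatory T cell core (18 of 19), colonic and tissue regulatory T cell (21 of 23), intraepithelial lymphocyte (16 of 17), naive and quiescence (16 of 16), memory and activation (24 of 24), Th1 (9 of 9), Th2 (5 of 9), Th17 (9 of 10), follicular helper (9 of 10), T cell receptor signal and immediate early (19 of 20), T cell receptor complex (19 of 19), interferon stimulated (27 of 27), cytokine receptor signalling (21 of 21), chemokine and homing receptors (22 of 22), inhibitory receptors (10 of 11), cell cycle (22 of 23), heat shock (12 of 13), recent thymic emigrant (9 of 12), chromosomal neighbours of Zbtb7b (24 of 34), sex linked (4 of 5), ribosomal protein (81 of 86), mitochondrially encoded (21 of 37) and T cell receptor variable segments (59 of 90), and markers of B cells (11 of 12), plasma cells (5 of 9), NK cells (7 of 10), NKT and innate-like T cells (6 of 7), gamma delta T cells (6 of 8), macrophages (12 of 14), dendritic cells (8 of 10), neutrophils (2 of 10), erythroid cells (5 of 9), platelets (2 of 7) and stroma (4 of 7). Older symbols were matched where the table uses them, such as Folr4 for Izumo1r and Tcrg-C1 for Trgc1. Each list was tested with limma camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. The CD4 lineage list includes Cd4 and the CD8 lineage list Cd8a and Cd8b1, the coreceptors that define the groups. The p-values of these 2 lists therefore rest in part on the sort. Counts of called members are given over all tested genes and adjusted over the list alone. Lists with fewer than 5 tested members have counts only. Unless an estimated correlation is named beside a list as ending its call, the call also held with it. A list's median is also given with members at 0 counts in a group set to their bound, 3 counts over the group, where that moves it.

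Named genes follow a fixed rule. Zbtb7b, Cd4, Cd8a, Cd8b1 and Runx3 are given whatever they show. For each comparison the highest and lowest 10 log2 fold changes (5 for CD4lo against DP and against WT CD8) were taken among called genes with an average log2 CPM of at least 3 and both libraries of one group above both of the other. Predicted models, receptor segments, ribosomal and mitochondrial genes were left out of these; they made up 243 of 2006, 212 of 1639, 234 of 1759, 165 of 1524, 7 of 166, 91 of 612, 84 of 515 and 75 of 436 such genes in the order of the comparisons (WT CD8, CD4hi, DP and CD4lo against WT CD4, DP against CD4hi, CD4lo against CD4hi, against DP and against WT CD8). From each list up to 4 called members with the smallest adjusted p were taken. Where a group had 3 or fewer counts of a gene, its counts are given and no fitted fold.

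The wild-type signature held the genes called in WT CD8 against WT CD4 with a log2 fold of at least 1, tested with camera in the contrasts between mutant groups; an index per library is the mean z of its higher genes minus that of its lower genes. Overlaps with shared WT CD4 controls were set against the overlap of independent lists and against 20 simulations of unchanged groups with the same controls. Marker levels are sums of CPM.

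The tests were tested on simulated data, negative binomial counts at each gene's mean level and dispersion with known folds added. For DP against CD4hi they recovered 37.3% of 1.5-fold, 68.7% of 2-fold and 92.4% of 4-fold changes, with 13 unchanged genes called, and in CD4lo against CD4hi, where recovery was lowest, 28.4%, 53.7% and 72.7%, with 6 called. Each comparison drew its own changed genes at random from the same levels and dispersions, so these differences in recovery do not rank the comparisons. In all 8 comparisons the raised list was recovered and 0 of 27 unchanged lists were called by camera. The simulated genes varied independently and the lists were random, so this cannot show false list calls that come from correlated genes.

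Alternatives were median-of-ratios size factors, DESeq2, no filter, a CPM filter, only the 4 libraries compared, a replicate block, leaving out ribosomal, mitochondrial and receptor genes, a test against a fold of 1.5, and leaving out each library in turn. In the latter the single library left in a group is assumed to vary like the other groups. The gene filter was applied anew in each of these runs, so the genes tested, the list members and the signature genes can differ from those of the main fit. Added after the data were seen were runs without CD4hi 1 and WT CD4 2 together, with protein-coding genes only, and a signature without the genes that set WT CD4 apart, and 2 further comparisons with WT CD8.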

Results

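Gene expression was measured by RNA sequencing in 10 libraries of naive mouse T cells, 2 libraries in each of 5 groups. The cells were sorted from spleen at 6 weeks of age as TCRb-positive lymphocytes without CD25 and CD44. Wild-type mice gave CD4 cells (WT CD4) and CD8 cells (WT CD8). Mice of the homozygous OB11 genotype gave cells with high CD4 (CD4hi), cells with both CD4 and CD8 (DP) and cells with low CD4 (CD4lo). The series title places the work around the autoregulatory loop of ThPOK, the zinc finger factor encoded by Zbtb7b, in mature CD4 T cells, and the labels do not say what the OB11 allele changes. Total counts were 5626750 and 6944197 in WT CD4, 5055956 and 7288738 in WT CD8, 5919128 and 5990718 in CD4hi, 6511952 and 7174290 in DP, and 7417789 and 5129677 in CD4lo. No label says that the 2 libraries of a group come from separate animals, so the p-values measure the spread between these libraries only. Fold changes are log2 values ± SE from the edgeR fit with n = 2 libraries per group, and levels are mean TMM-normalised CPM, the counts of a gene scaled to a common library size, ± SD, n = 2. The titles of the WT CD4 and CD4lo libraries carry a mark L, which lies with whole groups. CD4lo against WT CD4 and DP against CD4hi compare libraries of the same mark, and for the other 6 comparisons the mark and the group cannot be told apart.

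Zbtb7b was present at 151 ± 9.31 CPM in WT CD4 cells and 2.84 ± 0.170 CPM in WT CD8 cells. All mutant groups lay between them, with 27.8 ± 0.148 CPM in CD4hi, 8.12 ± 1.5 CPM in DP and 9.0 ± 0.542 CPM in CD4lo cells, or 18.4%, 5.37% and 5.95% of the WT CD4 mean. Cd4 stood at 641 ± 41.8 CPM in WT CD4, 483 ± 52.5 in CD4hi, 242 ± 9.73 in DP, 34.0 ± 1.14 in CD4lo and 2.89 ± 1.62 in WT CD8. Cd8a, the alpha chain of the CD8 coreceptor, reached 604 ± 3.43 CPM in WT CD8 and 258 ± 2.82 in DP, against 2.16 ± 2.05 in WT CD4, 1.31 ± 0.420 in CD4hi and 2.75 ± 0.285 in CD4lo. Cd8b1, the beta chain, was higher in CD4lo (60.5 ± 6.68 CPM) than in WT CD4 (11 ± 1.02) and CD4hi (22.4 ± 3.95), and reached 278 ± 4.08 in DP and 520 ± 5.60 in WT CD8. Runx3, a factor of the CD8 lineage, rose from 125 ± 8.26 CPM in WT CD4 to 179 ± 1.41 in CD4hi, 209 ± 12.4 in DP, 256 ± 4.39 in CD4lo and 239 ± 6.43 in WT CD8, each with an edgeR adjusted p of at most 0.000284 against WT CD4. On mouse build mm10 the GENCODE annotation places Zbtb7b on chromosome 3 (89377644 to 89394776), Cd4 (124864692 to 124888221), Cd8a (71373427 to 71379173) and Cd8b1 (71322788 to 71337494) on chromosome 6, and Runx3 on chromosome 4 (135120652 to 135177990), all as protein-coding genes.

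**Figure D1:**
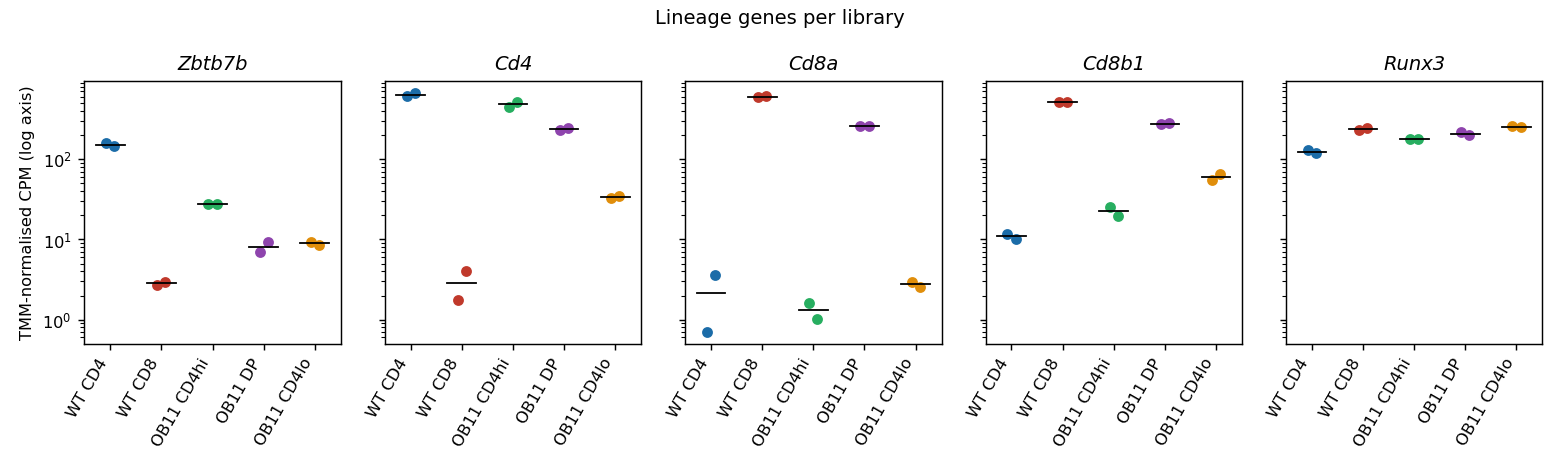
Level of Zbtb7b, Cd4, Cd8a, Cd8b1 and Runx3 in each library, in TMM-normalised CPM on a log axis, by group, with points for libraries and a line for the mean of 2. Zbtb7b falls from 151 CPM in WT CD4 to 27.8 in CD4hi, 9.0 in CD4lo, 8.12 in DP and 2.84 in WT CD8.

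WT CD8 against WT CD4 cells gives the reference difference between the wild-type groups, which also differ in the L mark. Zbtb7b was lower in CD8 cells by a fold of 52.5 (-5.72 ± 0.14, adjusted p = 1.72e-12), and Cd40lg, the helper ligand CD154, was lower by -3.79 ± 0.15. Genes of the CD8 program were higher, among them Ly6c2 (6.39 ± 0.19), the lectin-like receptor gene Klrk1 (5.21 ± 0.29), the chemokine Ccl5 (3.37 ± 0.14) and the T-box factor Eomes (3.21 ± 0.17). Transcripts of regulatory T cells were far lower in CD8 cells, as for the factor Foxp3 (-6.12 ± 0.20), Nrp1 (-6.11 ± 0.19), the IL-2 receptor chain Il2ra (-4.42 ± 0.18) and Ikzf2 (-3.38 ± 0.13). Lrrc32 had 3 counts over both CD8 libraries against 318 in WT CD4. Interferon-stimulated genes were higher in CD8 cells, with Mx1 at 3.28 ± 0.18, Ifit3 at 3.02 ± 0.12 and Ifit1 at 1.87 ± 0.10. This was not particular to CD8 cells, since 24 of the 27 listed interferon genes set WT CD4 apart from every mutant group as well. The libraries themselves decided some sizes, since Cd4 changed by -7.70 ± 0.18 with all libraries and -8.49 without WT CD8 2, and Cd8a rose by 8.01 ± 0.23 with all, 7.39 without WT CD4 1 and 9.69 without WT CD4 2.

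Of the fixed gene lists, CD4 lineage had 9 of 10 tested members lower and 1 higher in WT CD8 cells (median -1.21, camera adjusted p = 1.09e-40), and CD8 lineage had 15 of 15 higher (median 2.74, adjusted p = 2.09e-84). Regulatory T cell core had 17 of 18 lower (median -3.13, or -2.52 with members at 0 in a group set to their bound, adjusted p = 4.43e-50). The interferon list had 25 of 27 higher (median 0.97, adjusted p = 1.48e-30), the intraepithelial lymphocyte list 8 higher and 1 lower of 16 (median 1.67, adjusted p = 4.24e-14), the Th1 list 7 of 9 higher (adjusted p = 2.82e-06) and the Th2 list 5 of 5 lower (adjusted p = 5.82e-06). These counts were, adjusted over the list alone, 9 lower and 1 higher, 15 higher, 18 lower, 25 higher, 8 higher and 2 lower, 8 higher and 5 lower. The memory list, with 11 higher and 4 lower of 24 (12 and 4 adjusted over the list alone), passed camera at 0.000136 but had adjusted p = 0.08 with an estimated correlation. B cell markers had 10 of 11 higher in WT CD8 cells (Cd79a 2.58 ± 0.25, Cd74 2.21 ± 0.17), with a camera adjusted p of 3.27e-12 and adjusted p = 0.051 with an estimated correlation, and their summed level was 535 ± 14.8 CPM in WT CD8 and 295 ± 34.9 in WT CD4.

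In all, 2651 of the 12193 genes tested by edgeR differed between the wild-type lineages, 1356 higher and 1295 lower in CD8 cells, 1058 of them by a fold of at least 2. The count fell to 1712 without WT CD8 1 and 1411 without WT CD8 2. In 59.7% of the tested genes the libraries of the compared groups did not overlap, where chance gives 33.3%.

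CD4hi against WT CD4 cells shows the mutant cells that kept high surface CD4. Zbtb7b was lower by -2.44 ± 0.10 (edgeR adjusted p = 6.54e-10). Icos, a costimulatory receptor, rose by 1.43 ± 0.09, Cd40lg changed by -1.04 ± 0.11, and Foxp3, a gene named for the other comparisons, stood at 80.7 ± 11.9 CPM beside 78.8 ± 5.21 in WT CD4. Genes of the CD8 lineage and of mucosal T cells rose, including Itgae, the CD103 integrin chain (2.54 ± 0.10), Ccl5 (2.77 ± 0.15), Eomes (2.51 ± 0.18), the gut-homing receptor Ccr9 (1.96 ± 0.15) and granzyme Gzmb (4.18 ± 0.45). The factors Maf (1.26 ± 0.08) and Rora (1.66 ± 0.15), the inhibitory receptors Lag3 (3.17 ± 0.21), Tigit (2.43 ± 0.22) and Ctla4 (0.87 ± 0.10), and the proliferation gene Mki67 (2.04 ± 0.12) rose as well. Among the genes with the largest changes were the phosphodiesterase Pde5a (4.69 ± 0.19) and Scg5 (3.72 ± 0.24), and, lower, Arsb (-3.01 ± 0.19), Ly6c1 (-2.68 ± 0.25), Slfn8 (-2.46 ± 0.11) and the thymocyte polymerase Dntt (-2.28 ± 0.27). Of these genes Arsb, Slfn8 and Itgae are among 115 that follow the L mark. Cd4 itself was lower by -0.41 ± 0.11 (adjusted p = 0.0215), a call lost without CD4hi 1 (-0.29, adjusted p = 0.176) and without WT CD4 2 (-0.34, adjusted p = 0.0582).

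The CD4 lineage list went both ways in CD4hi cells, 5 higher and 3 lower of 10, with a median of 0.15, a mean of -0.05 and a camera test directed down at an adjusted p of 0.942. CD8 lineage had 13 of 15 higher (median 1.30, adjusted p = 1.48e-29). The list of colonic and tissue regulatory T cells had 15 of 21 higher (median 1.66, adjusted p = 3.98e-26), while regulatory T cell core had 4 higher and 2 lower of 18 (adjusted p = 0.226). Memory and activation had 20 of 24 higher (median 1.14, Itgb1 1.36 ± 0.08, adjusted p = 3.5e-25), Th17 7 of 9 (median 1.83, adjusted p = 3.5e-13). Follicular helper genes had 7 of 9 higher (median 1.01, Cxcr5 1.46 ± 0.18, adjusted p = 5.05e-12), inhibitory receptors 6 of 10 (median 1.01, adjusted p = 4.8e-10) and cell cycle 12 of 22 (median 1.23, adjusted p = 7.51e-10). The interferon list had 25 of 27 higher (median 1.16, Ifit3 2.80 ± 0.12, Mx1 3.21 ± 0.18, adjusted p = 6.34e-37). In the same order the counts adjusted over the list alone were 5 higher and 3 lower, 13, 16, 4 higher and 2 lower, 21, 7, 9, 7, 12 and 27. The list of T cell receptor signals and immediate early genes had 9 higher and 1 lower of 19 (10 and 1 adjusted over the list alone, adjusted p = 2.73e-05), with adjusted p = 0.112 with an estimated correlation. Macrophage markers had 5 higher and 1 lower of 12 (8 and 1 adjusted over the list alone, median 1.11), with a camera adjusted p of 0.00514, 0.059 without WT CD4 1, and adjusted p = 0.147 with an estimated correlation. edgeR called 2048 genes between CD4hi and WT CD4, 1264 higher and 784 lower, 725 by a fold of at least 2, and 1193 without CD4hi 2. A fit of only these 4 libraries, which takes no estimate of the spread from the other groups, called 1202. The libraries did not overlap in 54.5% of genes, against 33.3% by chance.

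DP against WT CD4 cells shows mutant cells that carry both coreceptors. Zbtb7b was lower by -4.21 ± 0.12 (edgeR adjusted p = 1.61e-11) and Cd4 by -1.41 ± 0.11, while Cd8b1 was higher by 4.67 ± 0.12 and Cd8a by 6.79 ± 0.23 (6.17 without WT CD4 1 and 8.47 without WT CD4 2). Ccl5 (3.61 ± 0.14), Ccr9 (3.51 ± 0.13), Itgae (2.21 ± 0.10), Klrk1 (3.87 ± 0.34) and the perforin gene Prf1 (1.39 ± 0.12) rose. Transcripts of regulatory T cells fell, with Nrp1 at -1.99 ± 0.12, Foxp3 at -1.28 ± 0.11 and Il2ra at -1.23 ± 0.12. Pde5a (4.60 ± 0.19) and Bend4 (4.33 ± 0.24) were among the highest, and Rnf144a (-3.80 ± 0.25), Arsb (-3.04 ± 0.19) and the protease receptor F2rl1 (-2.74 ± 0.19) among the lowest. Itgae, Rnf144a and Arsb follow the L mark. Ifit3 rose by 3.24 ± 0.11 and Mki67 by 2.14 ± 0.12.

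CD8 lineage had 13 of 15 members higher in DP cells (median 2.83, camera adjusted p = 3.71e-64) and cytotoxic effector 12 higher and 1 lower of 16 (median 1.98, adjusted p = 4.07e-10). The intraepithelial lymphocyte list had 10 of 16 higher (median 2.25, adjusted p = 5.43e-24), memory 18 of 24 (adjusted p = 1e-11), interferon 25 of 27 (median 1.07, adjusted p = 8.23e-40) and cell cycle 12 of 22 (adjusted p = 9.91e-10). Regulatory T cell core had 11 lower and 1 higher of 18 (median -0.60, adjusted p = 1.4e-07). CD4 lineage had 5 lower and 2 higher of 10 (median -0.39, adjusted p = 1.05e-07), with adjusted p = 0.0502 with an estimated correlation. Taken in this order, the counts adjusted over the list alone were 13, 12 and 1, 14, 19, 26, 14, 11 and 2, and 6 and 3. Markers of other cell types moved with the group. Macrophage markers had 11 of 12 higher (11 adjusted over the list alone, Lyz2 3.82 ± 0.14, adjusted p = 1.68e-13) with a summed level of 369 ± 13.5 CPM in DP and 179 ± 13.9 in WT CD4. B cell markers had 8 of 11 higher (9 adjusted over the list alone, Cd74 2.14 ± 0.17, adjusted p = 1.48e-07; adjusted p = 0.093 with an estimated correlation) and summed to 437 ± 32.4 against 295 ± 34.9 CPM. Between DP and WT CD4 2332 genes differed, 1349 higher and 983 lower, 917 by a fold of at least 2. Without DP 1 the count was 1367 and without DP 2 it was 1254, and libraries did not overlap in 58.4% of genes, against 33.3% by chance.

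CD4lo against WT CD4 cells, libraries of the same title mark, joined the loss of Cd4 (-4.24 ± 0.13) and Zbtb7b (-4.06 ± 0.12, edgeR adjusted p = 2e-11) with a gain of Cd8b1 (2.46 ± 0.13) and Runx3 (1.04 ± 0.08) but no detected change of Cd8a (0.26 ± 0.41, adjusted p = 0.727). Klrk1 (6.13 ± 0.27), Ly6c2 (5.71 ± 0.20), Ccl5 (4.56 ± 0.13), the chemokine receptor Cxcr6 (3.93 ± 0.22) and Eomes (3.17 ± 0.17) were higher. Klrc1, an NK cell receptor gene, had 256 counts in CD4lo and 1 in WT CD4. Foxp3 (-5.85 ± 0.19), Nrp1 (-4.01 ± 0.15), the costimulatory receptor gene Tnfrsf4 (-2.27 ± 0.20), Ctla4 (-1.64 ± 0.12) and the factor Irf4 (-1.54 ± 0.13) were lower. Lrrc32 had 2 counts in CD4lo against 318 in WT CD4. Markers of gamma delta T cells stood far above WT CD4, with the scavenger receptor gene Cd163l1 at 43.0 ± 2.85 CPM against 0.892 ± 0.507 and the constant gene Tcrg-C1 at 31.2 ± 0.0667 against 0.872 ± 0.731. Their fitted changes of 5.50 ± 0.31 and 5.04 ± 0.35 became 6.28 and 6.38 without WT CD4 2.

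All 6 tested gamma delta markers were higher in CD4lo (median 5.01, camera adjusted p = 3.7e-29), as were 6 of 7 NK cell markers (median 3.17, adjusted p = 1.2e-11) and 9 of 9 Th1 genes (median 2.16, adjusted p = 2.51e-13). CD8 lineage had 13 of 15 higher (median 2.46, adjusted p = 2.93e-59), cytotoxic effector 11 of 16 (median 1.69, adjusted p = 1.22e-18), memory 21 of 24 (median 1.33, adjusted p = 5.38e-44), Th17 6 higher and 1 lower of 9 (median 3.23, adjusted p = 4.16e-10) and interferon 26 of 27 (median 1.03, adjusted p = 8.19e-40). CD4 lineage had 7 of 10 lower (median -0.57, adjusted p = 8.61e-25) and regulatory T cell core 11 of 18 lower (median -1.59, adjusted p = 1.39e-34). For these lists in order, adjusted over the list alone, the counts were 6, 6, 9, 13, 13, 23, 6 and 1, 26, 7 and 14. Macrophage and B cell markers did not pass here (camera adjusted p = 0.187 and 0.215, with 2 higher and 1 lower of 12 and 1 higher and 1 lower of 11, the same counts adjusted over the list alone). Between CD4lo and WT CD4 1931 genes differed, 1075 higher and 856 lower, 710 by a fold of at least 2, and 1239 without CD4lo 2. Libraries did not overlap in 54.0% of genes, against 33.3% by chance.

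**Figure D2:**
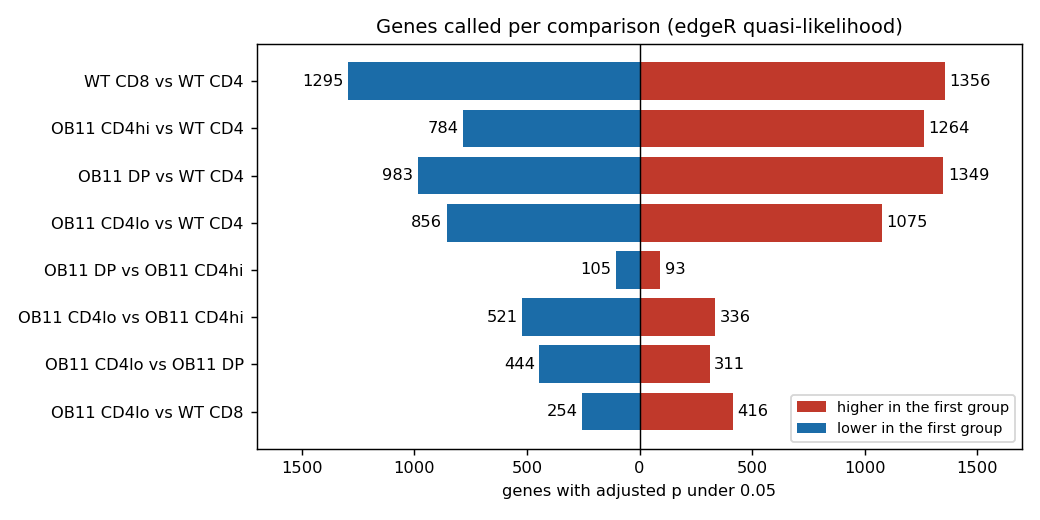
Number of genes that passed the edgeR test in each of the 8 comparisons, with bars to the right for genes higher and to the left for genes lower in the first group named. The counts run from 2651 for WT CD8 against WT CD4 down to 198 for DP against CD4hi.

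The comparisons with WT CD4 shared many genes. WT CD8 and DP had 885 higher genes in common where independent lists would share 150, and 642 lower genes where 104 would be shared. WT CD8 and CD4lo shared 790 higher (120 expected) and 622 lower genes (90.9 expected), and WT CD8 and CD4hi 780 (141 expected) and 459 (83.3 expected). Among the mutant groups CD4hi and DP shared 965 higher and 530 lower genes (140 and 63.2 expected), DP and CD4lo 748 and 495 (119 and 69.0 expected), and CD4hi and CD4lo 695 and 390 (111 and 55.0 expected). Of the genes changed against WT CD4, 60.5% in CD4hi, 65.5% in DP and 73.1% in CD4lo had changed the same way in WT CD8 cells. In the same order, 90, 42 and 17 genes had changed the opposite way. Part of the excess may come from the shared controls, but unchanged groups simulated against the same controls shared only 0.15 higher and 0.05 lower genes on average. That simulation covers sampling noise in the controls and no real difference of WT CD4 from all other groups. By definition the 837 genes that set WT CD4 apart from all 4 groups are counted as shared in every pair, such as 837 of 1085 for CD4hi with CD4lo and 837 of 1239 for WT CD8 with CD4hi. The covariance of the fold changes across genes was 0.577, 0.945 and 0.840 for WT CD8 with CD4hi, DP and CD4lo, and 0.657, 0.437 and 0.746 for CD4hi with DP, CD4hi with CD4lo and DP with CD4lo, against 0.0686 in the simulations. The correlation of the fold changes, which shared controls alone bring to 0.501 in the simulations, was 0.617, 0.795 and 0.695 for the former pairs and 0.776, 0.507 and 0.682 for the latter, so for CD4hi with CD4lo it lay at the simulated value. The sums of shared higher and lower genes changed with 1 library left out. For WT CD8 with CD4hi 1239 became 809 without WT CD8 2 and 777 without CD4hi 2, for WT CD8 with DP 1527 became 978 without WT CD8 2 and 965 without DP 2, and for WT CD8 with CD4lo 1412 became 936 without WT CD8 2. For CD4hi with DP 1495 became 974 without CD4hi 2 and 949 without DP 2, for CD4hi with CD4lo 1085 became 701 without CD4hi 2, and for DP with CD4lo 1243 became 802 without DP 2.

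Slfn8, Arsb and the interferon genes belonged to a set of 837 genes in which WT CD4 cells differed from each of the other 4 groups, 292 higher and 545 lower in WT CD4. Among them was the histone gene Hist1h2al, with 0 counts in WT CD4, where a count of 0 allows up to 3, and 219 in WT CD8, 251 in CD4hi, 394 in DP and 309 in CD4lo. Trim30c had 2 counts in WT CD4 and 317, 106, 166 and 249 in the same groups. WT CD8, CD4hi, DP and CD4lo were set apart from all others by 180, 47, 20 and 62 genes, in that order. Of the interferon list, 24 of 27 genes were in the WT CD4 set.

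DP against CD4hi, mutant cells of the same title mark, shows what went with gaining CD8. Cd8a (7.61 ± 0.25) and Cd8b1 (3.63 ± 0.11) were higher in DP, and Zbtb7b (-1.77 ± 0.14, edgeR adjusted p = 4.01e-06) and Cd4 (-1.0 ± 0.11) lower. Ccr9 (1.55 ± 0.11), Nkg7 of cytotoxic granules (1.31 ± 0.16) and Ccl5 (0.84 ± 0.10) were higher, as was Dntt (3.08 ± 0.25). Foxp3 (-1.31 ± 0.11), Il2ra (-1.37 ± 0.12), Maf (-1.27 ± 0.08), Icos (-0.90 ± 0.09), Cd5, a negative regulator of receptor signalling (-0.82 ± 0.08), Prg4 (-2.45 ± 0.18) and F2rl1 (-2.13 ± 0.20) were lower. Runx3 did not pass the test (0.23 ± 0.08, adjusted p = 0.227).

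Regulatory T cell core had 11 of 18 members lower in DP (median -0.78, camera adjusted p = 2.64e-39), CD4 lineage 5 of 10 lower (median -0.65, adjusted p = 3.6e-28), Th17 5 of 9 lower (median -1.27, adjusted p = 5.87e-19), and the colonic and tissue regulatory T cell list 5 lower and 1 higher of 21 (median -0.65, adjusted p = 6.11e-13). Memory had 8 of 24 lower (median -0.29, adjusted p = 1.12e-07). CD8 lineage had 4 higher and 1 lower of 15 (median 0.32, adjusted p = 9.11e-36) and cytotoxic effector 3 higher and 1 lower of 16 (median 0.59, adjusted p = 3.42e-06). The CD8 lineage test includes Cd8a and Cd8b1, and the CD4 lineage test Cd4, which define the groups. Adjusted over the list alone, the counts in this order were 14, 8, 7, 11 and 1, 13 lower and 3 higher, 9 and 4, and 9 and 1. Macrophage markers had 3 of 12 higher in DP (9 adjusted over the list alone; Lyz2 2.02 ± 0.12, adjusted p = 3.95e-22) and B cell markers 4 of 11 (7 adjusted over the list alone; Cd79a 2.22 ± 0.30, adjusted p = 9.58e-19). Of the tested genes 198 differed, 93 higher and 105 lower, 86 by a fold of at least 2. The count was 122 without CD4hi 1, 98 without CD4hi 2, 97 without DP 1 and 69 without DP 2. Of these genes 62.1% (54 higher and 69 lower) had changed the same way in WT CD8 against WT CD4. A further 12 higher and 7 lower genes had changed the opposite way there. Libraries did not overlap in 41.8% of all tested genes, against 33.3% by chance.

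CD4lo against CD4hi set apart the mutant groups with the lowest and the highest Cd4. Cd4 was lower in CD4lo by -3.83 ± 0.13 and Zbtb7b by -1.62 ± 0.14 (edgeR adjusted p = 2.19e-06), and Cd8b1 (1.43 ± 0.12) and Runx3 (0.52 ± 0.08) were higher. Foxp3 (-5.88 ± 0.19), Tigit (-3.70 ± 0.26), Nrp1 (-3.23 ± 0.16), Lag3 (-3.02 ± 0.21), the follicle-homing receptor Cxcr5 (-2.64 ± 0.21), Ctla4 (-2.51 ± 0.11), Irf4 (-2.29 ± 0.12), Icos (-1.81 ± 0.09) and Itgae (-1.27 ± 0.09), which follows the L mark, were lower. The helper cytokine gene Il21 had 1 count in CD4lo and 134 in CD4hi. Klrk1 (3.69 ± 0.21), Atp8b4 (2.52 ± 0.14), Cxcr6 (2.52 ± 0.19), Klrd1 (2.04 ± 0.17), Ly6c2 (1.80 ± 0.13) and Ccl5 (1.79 ± 0.10) were higher. The NK receptor gene Ncr1 had 157 counts in CD4lo and 2 in CD4hi.

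Regulatory T cell core had 15 of 18 members lower in CD4lo (median -1.96, camera adjusted p = 5.11e-73), CD4 lineage 9 of 10 (median -0.88, adjusted p = 5.95e-44), follicular helper 8 of 9 (median -1.81, adjusted p = 1.8e-33), inhibitory receptors 7 of 10 (median -1.56, adjusted p = 1.18e-25) and T cell receptor signal 7 of 19 (adjusted p = 8.07e-10). Gamma delta markers had 6 of 6 higher (median 5.25, adjusted p = 2.06e-36), NK markers 6 of 7 (median 3.16, adjusted p = 4.94e-13). CD8 lineage had 8 higher and 1 lower of 15 (median 0.66, adjusted p = 3.41e-14), cytotoxic effector 7 higher and 2 lower of 16 (adjusted p = 8.07e-10) and memory 10 higher and 2 lower of 24 (adjusted p = 2.98e-08). Adjusted over the list alone, the counts in this order were 15, 9, 9, 7, 11, 6, 7, 9 and 1, 11 and 2, and 15 and 3. The Th17 list went both ways, 3 higher and 3 lower of 9 (4 and 3 adjusted over the list alone), with a median of 0.55 and a camera test directed down at an adjusted p of 0.664. Of the tested genes 857 differed, 336 higher and 521 lower, 418 by a fold of at least 2. The count was 532 without CD4hi 1, 533 without CD4lo 1 and 507 without CD4lo 2. Of these genes 37.8% (114 higher and 210 lower) had changed the same way in WT CD8 against WT CD4. A further 68 higher and 109 lower genes had changed the opposite way there. Libraries did not overlap in 47.4% of tested genes, against 33.3% by chance.

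CD4lo against DP compared mutant groups whose Zbtb7b did not differ detectably (0.15 ± 0.16, edgeR adjusted p = 0.752). Cd8a (-6.53 ± 0.22), Cd8b1 (-2.21 ± 0.10) and Cd4 (-2.83 ± 0.13) were lower in CD4lo, with Foxp3 (-4.57 ± 0.22) and Tigit (-3.06 ± 0.26). Ccr2, a receptor of inflammatory homing (2.48 ± 0.23), Klrk1 (2.26 ± 0.17) and Ly6c2 (2.16 ± 0.13) were higher. Cd163l1 was at 43.0 ± 2.85 CPM in CD4lo and 0.298 ± 0.0219 in DP. Gamma delta markers had 6 of 6 higher (median 4.59, camera adjusted p = 1.65e-49), memory 17 higher and 2 lower of 24 (median 0.62, adjusted p = 1.25e-22) and Th17 5 of 9 higher (median 2.08, adjusted p = 5.74e-08). Regulatory T cell core had 10 of 18 lower (median -0.90, adjusted p = 7.68e-23), follicular helper 6 of 9 (adjusted p = 2.58e-18) and inhibitory receptors 5 of 10 (adjusted p = 5.08e-16). CD8 lineage had 6 higher and 3 lower of 15, with a median of 0.29 but a mean of -0.24 and a camera test directed down (adjusted p = 0.189). Its members Cd8a (-6.53) and Cd8b1 (-2.21), which define the groups, were among the lower. Macrophage markers had 9 of 12 lower in CD4lo (median -2.53, Lyz2 -2.18 ± 0.12, adjusted p = 2.34e-18). Adjusted over the list alone, the counts in this order were 6, 19 and 2, 6 higher and 3 lower, 13 lower and 1 higher, 9, 7, 7 and 4, and 10. Of the tested genes 755 differed, 311 higher and 444 lower, 389 by a fold of at least 2. The count was 418 without DP 1, 371 without DP 2, 429 without CD4lo 1 and 476 without CD4lo 2, and 1151 without both CD4hi 1 and WT CD4 2, a setting added after the data were seen. Of these genes 30.2% (91 higher and 137 lower) had changed the same way in WT CD8 against WT CD4. A further 82 higher and 150 lower genes had changed the opposite way there. Libraries did not overlap in 48.2% of tested genes, against 33.3% by chance.

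CD4lo against WT CD8 cells asked how close the CD4lo cells lay to the CD8 lineage. Cd8a (-7.75 ± 0.22, edgeR adjusted p = 2.09e-11) and Cd8b1 (-3.11 ± 0.10) were lower, Zbtb7b was higher by 1.66 ± 0.21, Cd4 by 3.46 ± 0.20 (4.26 without WT CD8 2), and Runx3 did not pass (0.10 ± 0.08, adjusted p = 0.625). The memory genes S100a4 (5.56 ± 0.34) and Cd44 (1.32 ± 0.08) and the genes Maf (3.78 ± 0.13), Cd163l1 (4.98 ± 0.29) and Il2ra (2.86 ± 0.21) were higher in CD4lo. The cytokine receptor gene Il1r1 had 165 counts in CD4lo and 2 in WT CD8. Th17 had 8 of 9 members higher (median 5.41, camera adjusted p = 4.9e-48), gamma delta markers 6 of 6 (median 5.12, adjusted p = 3.43e-52). Memory genes had 17 higher and 1 lower of 24 (median 0.82, adjusted p = 2.29e-36), CD4 lineage 7 of 10 (median 0.85, adjusted p = 2.4e-18) and regulatory T cell core 7 of 18 (median 0.45, adjusted p = 1.26e-12). CD8 lineage had 5 lower and 1 higher of 15 (median -0.25, adjusted p = 1.02e-19) and B cell markers 9 lower and 1 higher of 11 (median -2.48, Cd79a -3.05 ± 0.27, adjusted p = 1.32e-19). The CD8 lineage test includes Cd8a (-7.75) and Cd8b1 (-3.11), and the CD4 lineage test Cd4 (3.46), which define the groups. The interferon list had 1 of 27 higher (adjusted p = 0.998). Adjusted over the list alone, the counts in this order were 9, 6, 19 and 2, 8, 9 higher and 1 lower, 8 and 2, 10 and 1, and 1. Of the tested genes 670 differed, 416 higher and 254 lower, 391 by a fold of at least 2. The count was 380 without WT CD8 1, 353 without WT CD8 2 and 413 without CD4lo 2, and libraries did not overlap in 46.2% of tested genes, against 33.3% by chance.

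**Figure D3:**
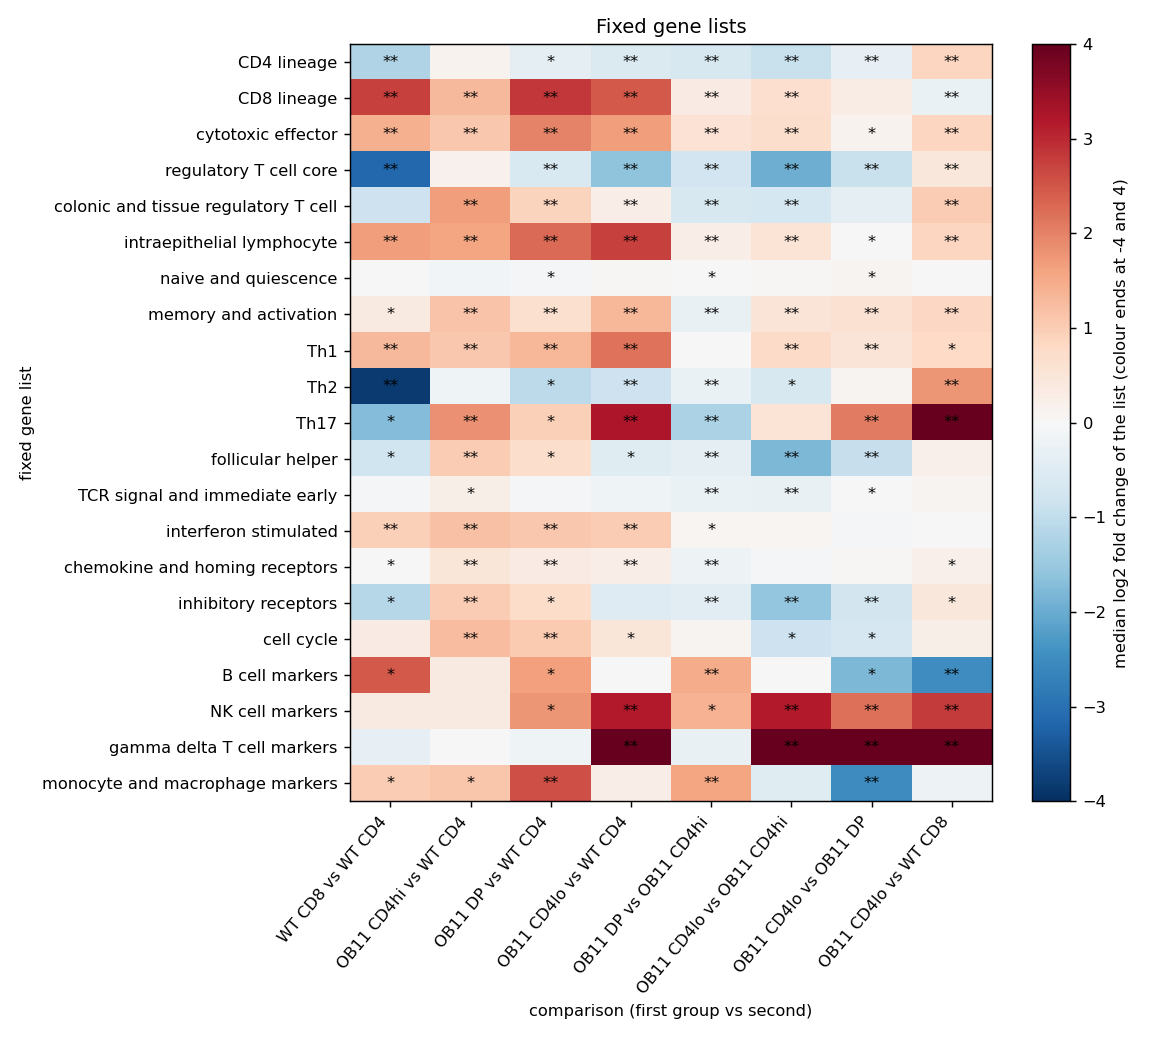
Median log2 fold change of the members of selected fixed gene lists (vertical axis) in each comparison (horizontal axis), from blue for lower to red for higher in the first group named, with a star for lists past the camera test and a double star for those that also pass with an estimated correlation. The gamma delta markers stand out in the 4 CD4lo columns, with medians from 4.59 to 5.25.

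On the wild-type signature each mutant group had an index between those of the wild-type groups. It held the 492 genes higher and 566 lower in WT CD8 than in WT CD4 by a fold of at least 2, and an index of each library was scaled so that WT CD4 is 0 and WT CD8 is 1. The index was 0.556 ± 0.0498 in CD4hi, 0.718 ± 0.00672 in DP and 0.618 ± 0.00774 in CD4lo (SD, n = 2). The same wild-type libraries chose the genes and set the scale, so a value between 0 and 1 is partly built in for any other group. No index of unchanged groups is given to set beside these values. The signature sets an L-marked group, WT CD4, against an unmarked one. Transcripts that follow the mark therefore pull the index of CD4lo down and those of CD4hi and DP up. No index without these transcripts was made, so the order of the mutant groups may depend on them. Without the genes that set WT CD4 apart from all other groups the index was 0.445 ± 0.0457, 0.652 ± 0.00312 and 0.455 ± 0.0138, in the same order. Those genes were chosen in these same libraries for differing from WT CD4 the same way in every other group. Leaving them out removes genes in which the mutant groups moved with WT CD8, so a lower index is built in. In the contrasts between mutant groups, which share no library with the signature, the CD8-type genes were higher in DP than in CD4hi (median 0.16, camera adjusted p = 1.88e-16) and lower in CD4lo than in DP (median -0.26, adjusted p = 3.22e-11). The latter call ended with protein-coding genes only, a setting added after the data were seen, which kept 324 of the 492 genes (median -0.01, adjusted p = 0.256), and with genes of any fold (adjusted p = 0.182). Without the genes that set WT CD4 apart it was larger (median -1.16, adjusted p = 3.34e-36), though that set was chosen in these same libraries and gives no independent check. The median was -0.15 without WT CD4 1, -0.14 without WT CD8 1, -0.15 without WT CD8 2 and -0.17 without DP 2. Many non-coding transcripts split along the L mark, which divides CD4lo from DP, with 74.5% of the typed genes that follow the mark not protein-coding. In CD4lo against CD4hi the median of the CD8-type genes was 0.01 while the camera test was directed down, at an adjusted p of 0.476. That direction turned with the gene set. It was up with protein-coding genes only (0.16, adjusted p = 1.63e-09) and down without the genes that set WT CD4 apart (-0.52, adjusted p = 6.59e-10), and neither passed with an estimated correlation. The CD4-type genes were lower in DP than in CD4hi (median -0.44, adjusted p = 1.89e-19) and lower in CD4lo than in CD4hi (median -0.50, adjusted p = 4.69e-12), but these medians were -0.15 and -0.15 without CD4hi 1 and -0.26 and -0.30 without WT CD4 2, and the one for CD4lo was -0.31 without WT CD8 2. Between CD4lo and DP they did not pass (median -0.07, or -0.06 with genes at 0 set to their bound, adjusted p = 0.454). With an estimated correlation the passing sets of the full signature had adjusted p values of 0.0234 for DP against CD4hi and 0.0288 for the others.

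**Figure D4:**
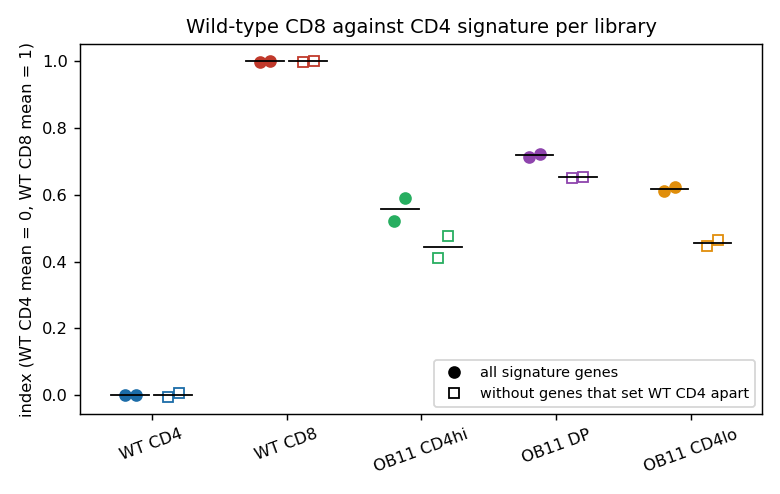
Wild-type signature index of each library by group, scaled so that WT CD4 is 0 and WT CD8 is 1, with filled points for all signature genes, open squares without the genes that set WT CD4 apart, and lines for the mean of 2 libraries. The mutant groups lie between, at 0.556 (CD4hi), 0.618 (CD4lo) and 0.718 (DP) with all genes and at 0.445, 0.455 and 0.652 without that set. Values between 0 and 1 are partly built in, as the same wild-type libraries chose the genes and set the scale. The fall without that set is built into how the set was chosen, and genes that follow the L mark pull CD4lo towards WT CD4.

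Transcripts of cell types other than conventional T cells differed between the groups. The summed gamma delta markers were 153 ± 1.89 CPM in CD4lo and 6.13 ± 3.14 in WT CD4, 7.51 ± 1.12 in WT CD8, 19.9 ± 0.763 in CD4hi and 10.2 ± 0.0283 in DP. Summed B cell markers were highest in WT CD8 (535 ± 14.8 CPM) and DP (437 ± 32.4), with 295 ± 34.9 in WT CD4, 287 ± 0.542 in CD4hi and 272 ± 19.0 in CD4lo. Summed macrophage markers were highest in DP (369 ± 13.5 CPM), with 233 ± 3.12 in CD4hi, 218 ± 9.86 in WT CD8, 205 ± 6.67 in CD4lo and 179 ± 13.9 in WT CD4. Trac, the constant gene of the alpha chain, was lower in CD4lo than in CD4hi (-0.79 ± 0.12, edgeR adjusted p = 0.000571), while the beta chain genes Trbc1 (-0.06, adjusted p = 0.837) and Trbc2 (0.16, adjusted p = 0.499), chosen after their values were seen, did not pass. Against WT CD4 both Trac (-0.80 ± 0.12, adjusted p = 0.000236) and Trbc1 (-0.44 ± 0.12, adjusted p = 0.0201) were lower in CD4lo. Trdv4, a variable gene of the delta chain, had 138 counts in CD4lo against 3 in WT CD4, 2 in WT CD8, 1 in CD4hi and 4 in DP.

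**Figure D5:**
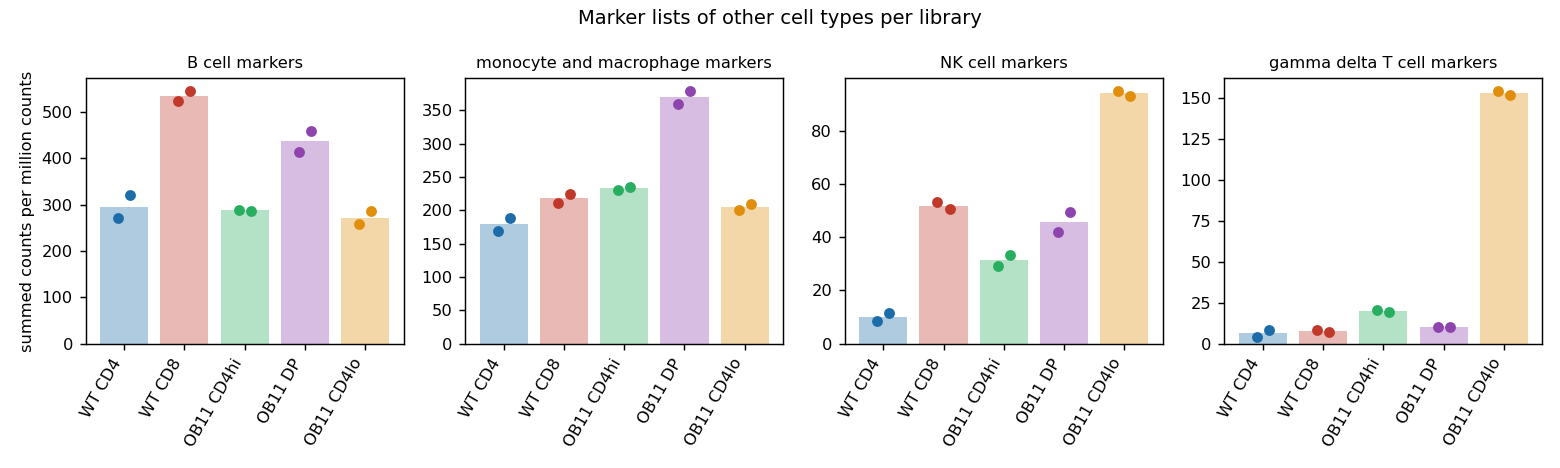
Summed level of the marker genes of other cell types in each library, in CPM from 0, by group, with points for libraries and a bar for the mean of 2. Gamma delta markers reach 153 CPM in CD4lo and at most 19.9 in the other groups, and macrophage markers 369 CPM in DP.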

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

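The background-read and graded-response tests of WT CD4 were written before their results were seen, and the other tests in this part were chosen only after. Genes that changed in opposite directions against WT CD4 in a pair of mutant groups, and also differed between the groups in the direct edgeR contrast, were counted. There were 7 such genes between DP and CD4hi, among them Dntt (0.80 in DP, -2.28 in CD4hi), Prg4, Ikzf2 and Nav2. The Dntt call in DP was lost without DP 2 (0.73, adjusted p = 0.0842). Between CD4lo and CD4hi there were 48, of which 42 were lower and 6 higher in CD4lo. They included Ctla4 (-1.64 in CD4lo, 0.87 in CD4hi), Irf4 (-1.54 and 0.75), Ikzf2 (-1.36 and 0.58) and, the other way, Atp8b4 (0.96 and -1.56). Between CD4lo and DP there were 27, 22 lower and 5 higher in CD4lo, among them Tigit (-1.27 in CD4lo, 1.78 in DP) and Atp8b4 (0.96 and -0.97). Prg4, Nav2 and Atp8b4 were chosen here after their values were seen. Their values against WT CD4, and that of Tigit in CD4lo, were not tested with libraries left out.

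WT CD4 cells differed from each of the other 4 groups in 837 genes, with 24 of the 27 interferon genes, 12 of 15 CD8 lineage genes and 3 of 10 CD4 lineage genes among them. Reads spread over many genes in WT CD4 2 do not account for this, since 73.0% of the 837 genes (611) were still called the same way in all 4 contrasts without that library. A different genetic background of the WT CD4 mice may contribute and stays open, because 34 genes were at least 8-fold apart from all 4 groups and within 2-fold among these, against 9 for the next group, and the design has a single wild-type CD4 group. It would require WT CD4 mice that differ from the WT CD8 mice, also wild type, which the labels do not state. The count does not single out a background, since WT CD4 is also the only group with the full level of Zbtb7b. It also goes with the size of the set and not with a larger share, being 34 of 837 genes for WT CD4 and 9 of 62 for CD4lo. A graded response to the level of Zbtb7b may contribute as well, since on a scale from WT CD4 (0) to WT CD8 (1) these genes lay at 0.887 ± 0.0414 in CD4hi, below 0.950 ± 0.0193 in DP and 0.932 ± 0.00225 in CD4lo (SD, n = 2). CD4hi 1, a library with reads spread over many genes, carries most of that gap, at 0.858 against 0.916 in CD4hi 2 and 0.931 in CD4lo 2.

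CD4lo cells carried summed gamma delta and NK cell markers at levels that no other group reached. B cells or macrophages in the CD4lo gate are argued against, because the higher CD4lo library had 495 CPM of summed B cell and macrophage markers, under the lowest DP library at 774 CPM, and a batch shared by the L-marked libraries by the median of 5.01 for the gamma delta markers against WT CD4, which carries the same mark. Gamma delta T cells in the CD4lo gate may be a source and stay open, as 6 of the 6 tested markers were higher against every other group (2 of the 8 listed also stand in another list). By the edgeR test Trac was lower than in CD4hi (-0.79, adjusted p = 0.000571) and DP (-0.48, adjusted p = 0.0249), the latter a call lost without DP 1, DP 2 or CD4lo 2. The beta chain genes did not pass in these comparisons, with Trbc1 at -0.06 and -0.23 (adjusted p = 0.837 and 0.36) and Trbc2 at 0.16 and -0.08 (adjusted p = 0.499 and 0.796). Against WT CD4, however, Trbc1 was lower (-0.44, adjusted p = 0.0201), as was Trac (-0.80, adjusted p = 0.000236), while Trbc2 did not pass (-0.21, adjusted p = 0.267). Against WT CD8 Trac was lower (-0.43, adjusted p = 0.0476) and neither beta chain gene passed. The TCRb gate of the sort would remove gamma delta and NK cells alike. NK cells, whose markers summed to 94.0 ± 1.22 CPM in CD4lo and at most 51.8 ± 1.92 elsewhere, and conventional cells of CD4lo with these transcripts were not tested as sources and stay open. NKT and innate-like T cells were not tested either, and their markers summed to 204 ± 7.06 CPM in CD4lo, 187 ± 20.6 in CD4hi and 90.1 ± 5.21 in WT CD4.

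Part of the genes split along the L mark, with WT CD4 and CD4lo on one side. In 115 genes each L-marked group differed from each other group the same way, 40 higher and 75 lower. That total is not particular to the mark, since 111 genes set WT CD8 and CD4lo apart in this way and 82 CD4hi and DP. The large differences were. Along the L split 36 genes were at least 8-fold apart, against 6 at most for the other splits of 2 groups against 3 (10 splits in all). A library batch marked by L may therefore underlie the L split and stays open. Biology shared by WT CD4 and CD4lo is argued against for most of these genes, because 74.5% of those with an annotated type were not protein-coding, against 7.65% of tested genes, and 24 protein-coding genes stay open. Metazoa_SRP, a cytoplasmic RNA, stood at 131 ± 3.07 CPM in WT CD4 and 148 ± 31.2 in CD4lo against 3230 ± 458 in DP, for example.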

How the results depend on the processing

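Runs without CD4hi 1 and WT CD4 2 together, with protein-coding genes only and without the genes that set WT CD4 apart were chosen after the data were seen, and the others before the data were examined. Of 794 named gene results 461, and of 161 list calls 98, kept their direction and their side of the threshold under every alternative run, and no named gene changed its sign and no camera test of a list its direction. List medians did change sign, as for recent thymic emigrants in CD4lo against CD4hi (-0.20, and 0.20 without CD4hi 1). So did NKT and innate-like markers in CD4hi against WT CD4 (0.05, and -1.01 without WT CD8 1 and without WT CD8 2). The WT CD8 libraries are in neither group of that comparison, but leaving out a library can change which members pass the filter. Against a fold of 1.5 the counts were 797, 507, 601, 486, 41, 275, 274 and 270 (WT CD8, CD4hi, DP and CD4lo against WT CD4, DP against CD4hi, CD4lo against CD4hi, DP and WT CD8), fewer by the construction of that test. With only the 4 libraries compared, the counts were 2355, 1202, 2055, 1392, 289, 814, 1002 and 834, in the same order. Only the 1202 of CD4hi against WT CD4 lay outside 1.5 times the main count. Fewer samples alone do not account for it, since DP against CD4hi, CD4lo against DP and CD4lo against WT CD8 rose. With no filter, DP against CD4hi had 345, and without CD4hi 1 and WT CD4 2 CD4lo against DP had 1151. The cause was not tested. Counts under size factors, DESeq2, the CPM filter and protein-coding genes only stayed within 1.5 times. With each library left out in turn, the lone library being assumed to vary like the other groups, the counts ran from 1411 to 2654, 1193 to 1998, 1254 to 2312, 1239 to 1948, 69 to 260, 507 to 1088, 371 to 949 and 353 to 857, in the same order, and the list calls from 153 to 162. With an estimated correlation 100 lists passed. The median of all genes moved to as low as -0.28 with no filter and -0.33 under DESeq2, and by under 0.1 elsewhere. The labels do not pair the libraries: deviations of replicate 1 from 2 correlated across genes from -0.548 to 0.126 between groups, and a replicate block gave 2417, 1885, 2088, 1703, 156, 745, 641 and 602 genes and 162 lists.

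For the wild-type signature, the CD8-type genes in CD4lo against CD4hi had a camera test directed up with genes of any fold (0.0554, adjusted p = 0.087). They passed upwards with protein-coding genes only (0.16, adjusted p = 1.63e-09) and downwards without the genes that set WT CD4 apart (-0.52, adjusted p = 6.59e-10), but not with an estimated correlation (adjusted p = 0.063 and 0.0716). Leaving out each library gave 0.0131 to 0.0822, with the test directed up without WT CD8 1 (0.08). In CD4lo against DP they no longer passed with any fold (-0.000424) or protein-coding genes only (-0.00947), and moved further without the genes that set WT CD4 apart (-1.16, adjusted p = 3.34e-36; adjusted p = 0.0254 with an estimated correlation). The medians of the other passing sets with any fold were 0.05 and -0.12 in DP and -0.14 in CD4lo, each against CD4hi. The CD4-type genes in CD4lo against DP passed with protein-coding genes only (-0.18, adjusted p = 0.000362; adjusted p = 0.127 with an estimated correlation) and ran from -0.148 to 0.0146 with each library left out, with the test directed up without WT CD4 1 (-0.05). For these the cause was not tested. Of simulated 1.5-fold changes 28.4% to 44.8% were found, at this depth and with 2 libraries per group. Calls shared by pairs of comparisons with WT CD4 ran from 258 to 422 against a fold of 1.5, and none of the 6 shared counts stayed within 1.5 times under every alternative.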

Other observations

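The comparisons with WT CD8 of CD4hi and DP were chosen after the data were seen. Further fixed lists described the mutant cells. The lineage transcription factors went both ways in every comparison with WT CD4, with 7 higher and 3 lower of 19 in CD4hi (camera adjusted p = 0.256) and 7 higher and 4 lower in CD4lo (adjusted p = 0.136). In CD4hi, Myb rose by 1.25 ± 0.12 and Eomes by 2.51 ± 0.18. Chemokine and homing receptors had 14 higher and 4 lower of 22 in CD4hi against WT CD4 (median 0.48, adjusted p = 1.19e-10). They had 12 higher and 4 lower in DP (median 0.32, adjusted p = 1.44e-05) and 10 higher and 5 lower in CD4lo (median 0.27, adjusted p = 2.14e-06). Naive and quiescence genes had 5 higher and 1 lower of 16 in CD4lo against DP (adjusted p = 0.000497; adjusted p = 0.0924 with an estimated correlation). The IL-7 receptor gene Il7r stood at 0.77 ± 0.07. Cytokine receptor signalling did not pass in CD4hi against WT CD4 (adjusted p = 0.606, 3 higher and 4 lower of 21), where Il4ra fell by 0.87 on the log2 scale. Markers of NKT and innate-like T cells had 4 of 6 higher in CD4lo against WT CD4 (median 2.02, adjusted p = 3.47e-07). Adjusted over the list alone, the counts in this order were 7 and 3, 7 and 4, 16 and 4, 14 and 4, 11 and 5, 6 and 1, 3 and 4, and 4.

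T cell receptor complex genes had 7 of 19 lower in CD4lo against WT CD4 (adjusted p = 0.00719; 0.0948 without WT CD4 1; adjusted p = 0.273 with an estimated correlation), with Cd28 at -0.96 ± 0.09. Variable segments of the receptor had 13 lower and 2 higher of 59 in WT CD8 against WT CD4 (adjusted p = 0.00777; adjusted p = 0.08 with an estimated correlation). Heat shock genes had 6 higher and 2 lower of 12 in CD4lo against WT CD4 (adjusted p = 0.11) and genes of recent thymic emigrants 4 lower and 1 higher of 9 (adjusted p = 0.11). The chromosomal neighbours of Zbtb7b had 4 of 24 higher in CD4hi (adjusted p = 0.641) and 3 higher and 1 lower in CD4lo (adjusted p = 0.68) against WT CD4. The RNA editing gene Adar stood at 0.66 ± 0.07 and 0.55 ± 0.07 there. Ribosomal protein genes had 52 higher and 3 lower of 81 in CD4lo against WT CD4 (median 0.32, adjusted p = 1.55e-08; adjusted p = 0.381 with an estimated correlation). Rpl29 went the other way (-1.92 ± 0.16). Mitochondrially encoded genes had 1 higher and 1 lower of 21 there (adjusted p = 0.768). Dendritic cell markers had 4 of 8 higher in DP against WT CD4 (H2-Ab1 2.48 ± 0.21, adjusted p = 7.89e-05; adjusted p = 0.123 with an estimated correlation). Plasma cell markers had 1 of 5 higher there (adjusted p = 0.17) and erythroid markers 2 of 5 (adjusted p = 0.17). In WT CD8 against WT CD4, sex linked genes had 2 of 4 higher, neutrophil markers 0 of 2, platelet markers 1 of 2 lower and stromal markers 1 of 4 lower. These counts were, adjusted over the list alone and in order, 7 and 1 higher, 15 lower and 3 higher, 8 and 2, 5 and 1, 4, 3 and 1, 68 and 3, 0, 5, 2, 2, 3, 1 lower, 1 and 1.

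CD4hi differed from WT CD8 in 1209 genes (759 higher, 450 lower, 504 by a fold of at least 2) and DP in 835 (557 higher, 278 lower, 337 by a fold of at least 2), by the same edgeR test. With protein-coding genes only these were 1271 and 892. CD4lo differed from WT CD8 in 670 genes, and in 519 with protein-coding genes only.

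Libraries differed in how many genes had a count, with 23545 in CD4hi 1 and 25272 in WT CD4 2 against 15532 to 17345 in the others. Of 1247 olfactory receptor genes, 261 and 399 had a count in these libraries, against 14 to 35 in the others. Dcpp3 varied within groups, with 5858 counts in CD4hi 1 and 1181 in CD4hi 2, and 577 and 14 in CD4lo 1 and CD4lo 2. Reads of microRNA genes numbered 4096 to 6443 in the L-marked libraries and 728 to 1636 in the others.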
